A study of Bos taurus with 11 samples.

How the data were processed

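DNA methylation was measured by reduced-representation bisulfite sequencing (RRBS), in which DNA is cut with a restriction enzyme that favours CpG-rich fragments and treated with bisulfite, so that unmethylated cytosines are read as thymine and methylated cytosines as cytosine. The samples were liver biopsies of Holstein dairy calves taken at 42 days of age. Per the labels, 6 of the 11 libraries came from calves under postnatal cooling and 5 from calves under postnatal heat stress; the series design states 6 calves per group, and a sixth heat-stressed calf was not analysed here. Replicates are numbered within a group only to name them. The labels give no sire, sex, pen or batch. The calves were group housed, nothing used here says in how many pens, and pen and treatment may therefore coincide. P-values rest on the spread between these libraries, each counted as a separate calf. For sites and tiles that spread is moderated across features.

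Per the submitters' processing notes, FastQC 0.11.7, Trim Galore 0.4.4 and Bismark 0.20.1 were used with the bovine build ARS-UCD1.2; their settings, the trimming rules and any filter on duplicates or conversion are not given in the sources used here. Each deposited table lists single positions, taken here as cytosines of CpGs because most adjoin a partner on the next base, with the percent of methylated reads, as the authors computed it, beside the count of methylated reads and the count of unmethylated reads. The deposited percent equalled 100 times the methylated count over both counts at every position, within 7.1e-14 points. The deposited counts are raw, with no scaling between libraries. PCR reads without molecular identifiers are not independent molecules, so intervals from counts would cover counting error only.

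Counts of the 2 strands of a CpG were summed where adjacent positions in the union of all libraries formed a pair (3059260 pairs); 1720030 positions had a single strand, and 118860 positions (1.49%) in runs that could not be paired were left out. A CpG was tested when it was autosomal, had at least 10 reads in each of the 11 libraries and was in no library among the top 0.1% of CpGs by coverage. This left 1753958 CpGs, of which 1636501 had both strands summed. The median depth of a tested CpG was 37 to 55 reads per library. Counts of tested CpGs were also summed in fixed tiles of 1 kb with at least 3 tested CpGs, which gave 140601 tiles with a median of 307 to 451 reads per library. A methylation level is the methylated count over all reads, in percent, and a difference is the heat-stressed minus the cooled group mean, in percentage points. All coordinates are 1-based in ARS-UCD1.2.

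Mean levels were compared by an exact two-sided permutation test over all 462 ways to choose the groups, with Benjamini-Hochberg (BH) adjustment over the 11 classes of CpGs and separately over the 29 autosomes. The interval of a difference holds the shifts that this test does not exclude at 0.05. CpG sites and tiles were tested with a quasi-binomial logistic model of the counts with 1 term for the group. The dispersion of each feature was moderated across features by the empirical Bayes method of limma and kept at 1 or higher, and F test p-values were adjusted by BH over all features tested, with a threshold of 0.05. The test was written in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and its moderation was checked against limma 3.58.1. Alternative tests were run in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood test on methylated and unmethylated counts, common dispersion at sites from 150000 sampled sites) and limma on M-values, log2((methylated + 1) / (unmethylated + 1)).

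The test was tried on simulated data in which the heat-stressed level of 50 features per size was raised by 10, 20, 30 or 40 points. Among 1753958 simulated CpG sites, 0.0%, 12%, 62.0% and 80.0% of the changed sites were called, with 2 false calls among 79. Among 140601 simulated tiles, 14.0%, 62.0%, 90.0% and 100% were called, with 8 false calls among 141. The simulated libraries were independent, their spread was drawn from the fitted dispersion, and changed features came from a limited span of mean levels. No simulated pair of libraries was alike and no CpG was set up as a sequence variant, so the false calls may be too few for the real data.

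The groups, tests, thresholds, coverage limits, tile size and most alternatives (other coverage limits, each library left out, other dispersion rules, edgeR, limma, strands apart, other tiles) were chosen before the data were examined. The rule for named features was to give the 10 called features with the largest higher and the 10 with the largest lower level in heat-stressed calves, and, where fewer pass, the 10 of smallest p. The rule also asked for a gene with a symbol nearby. No gene annotation of ARS-UCD1.2 was used here and the table of gene names at hand is of another assembly, ARS-UCD2.0, so no position was assigned to a gene. For that reason promoters, gene bodies, lists of genes and the classes exon, intron and CpG island were not analysed here, and the rule was applied without its gene criterion. Classes made from the tables themselves took their place after the data were seen: the number of tested CpGs in the 1 kb tile, the mean level over the 11 libraries, the X chromosome and the unplaced scaffolds. Also chosen after seeing the data were the definition of an isolated variable CpG (a range over the 11 libraries of at least 40 points while the nearest tested CpG, within 50 bp, has a range under 20 points), the matching of CpGs on range (bins of 5 points) and mean level (bins of 20 points), the sums of cooled replicates 3 and 6 and of other cooled pairs, and the comparisons between libraries, with their limit of 30 reads.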

Results

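Liver methylation was compared between Holstein calves that were heat-stressed (5 libraries) or cooled (6 libraries) from birth to weaning, to ask whether heat in early life leaves a mark on DNA methylation in the liver at 42 days of age. The libraries held 93947010 to 140706580 read calls at 5304765 to 6000896 cytosine positions, with a median of 13 to 18 reads per position. In the cooled libraries 1 to 6 the totals were 140410856, 127210800, 129548133, 136003357, 120714141 and 93947010, and in the heat-stressed libraries 1 to 5 they were 126785592, 126232068, 140706580, 130083723 and 115229993. The share of methylated reads was 52.2% to 54.8%. Between any pair of libraries the levels of the 1753958 tested CpGs correlated with r of 0.968 to 0.981 across CpGs.

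The livers of both groups showed the bimodal pattern of mammalian body cells. Of the tested CpGs, 32.3% had a mean level under 10%, 31.7% were at 90% or higher and 18.8% lay between 20 and 80%. The level fell as the number of tested CpGs in the tile rose, a number that reflects coverage as well as CpG density. In cooled calves the level was 77.0% ± 0.612 (SD, n = 6) in tiles with 1 to 4 tested CpGs and 69.9% ± 0.612 with 5 to 14. It was 51.0% ± 0.485 with 15 to 29, 28.3% ± 0.307 with 30 to 59 and 11.6% ± 0.216 with 60 or more. Tiles under 10% in all 11 libraries numbered 22979 (16.3% of tested tiles) and formed 283 runs of at least 4 kb. The longest run covered 12 kb of chromosome 25 (2620001 to 2632000), at 4.60% ± 0.518 in cooled and 4.60% ± 0.477 in heat-stressed calves. Runs of 7 kb lay on chromosome 2 (22448001 to 22455000), chromosome 11 (100946001 to 100953000) and chromosome 24 (37524001 to 37531000), among others.

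A smaller set of 4318 tiles (3.07%) stayed between 35 and 65% in all 11 libraries and formed 163 runs of at least 2 kb. The longest was a 6 kb run on chromosome 29 (49521001 to 49527000), at 47.2% ± 3.34 in cooled (n = 6) and 47.1% ± 1.68 in heat-stressed calves (n = 5). It was followed by a 4 kb run on chromosome 13 (57529001 to 57533000), at 52.3% ± 2.31 and 51.7% ± 2.04. Runs of 3 kb lay on chromosome 18 (63495001 to 63498000), at 45.7% ± 3.20 and 43.8% ± 3.32, and on chromosome 21 (65722001 to 65725000), at 48.2% ± 3.19 and 48.3% ± 1.64, as well as on chromosomes 7, 13, 16, 19 and 25. As background, cattle chromosomes 29, 13, 18 and 21 carry the imprinted IGF2-H19, GNAS, PEG3 and DLK1-MEG3 genes, whose control regions are methylated on a single parental allele. Whether the runs lie at those genes was not determined here. The limits of both kinds of run were set on all 11 libraries, so a tile that left them in either group is not part of a run, and the runs are no test of a difference between the groups.

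Mean methylation was nearly equal in heat-stressed and cooled calves. Over all tested autosomal CpGs the level was 52.3% ± 0.457 in cooled (n = 6) and 52.6% ± 0.255 in heat-stressed calves (n = 5), a difference of 0.282 points with an interval from -0.172 to 0.828 (two-sided exact permutation p = 0.279, adjusted p = 0.497). CpGs of intermediate level (20 to 80%) stood at 56.4% ± 0.813 and 57.0% ± 0.693 (exact permutation p = 0.219), and CpGs at 80% or more stood at 92.5% ± 0.847 and 92.9% ± 0.322 (exact permutation p = 0.381). The X chromosome had 42.2% ± 0.222 and 42.4% ± 0.206 (exact permutation p = 0.132), and reads on unplaced scaffolds were methylated at 69.9% ± 0.999 and 70.8% ± 1.54 (exact permutation p = 0.312). None of the 11 classes passed after adjustment (smallest adjusted p = 0.497), nor did any autosome, the nearest being chromosome 9 with an unadjusted exact permutation p of 0.0952. Cooled replicate 4 had the lowest mean level, 51.5%, and without it the difference was 0.121 points. The difference was 0.525 points with methylated reads over all reads, 0.480 over all CpGs with at least 10 reads in the library at hand and 0.275 (exact permutation p = 0.341) with cooled replicates 3 and 6 as 1 value, and none of these passed the threshold.

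**Figure D1:**
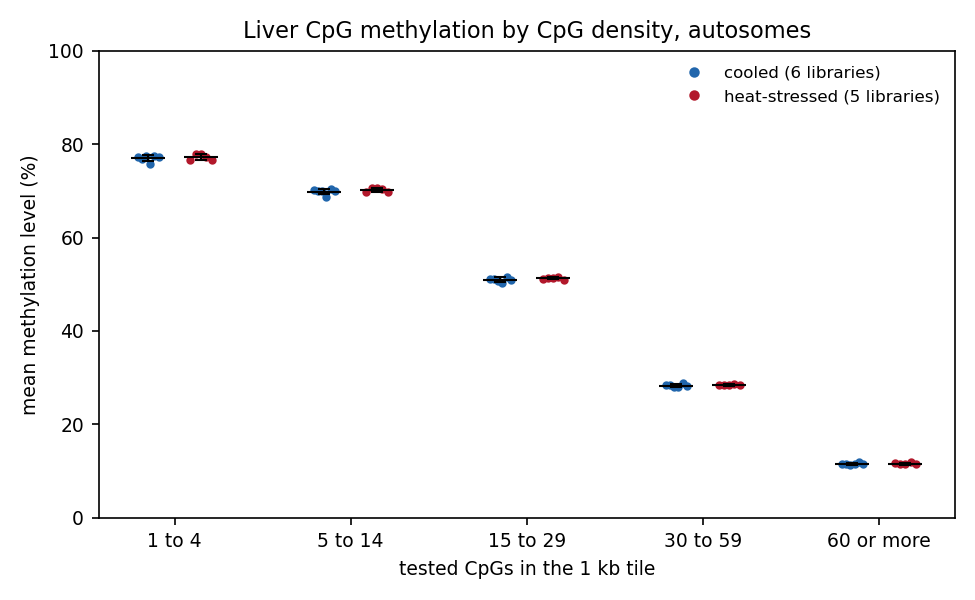
Mean methylation level (%) of tested autosomal CpGs against the number of tested CpGs in their 1 kb tile. Each point is 1 library (blue cooled, red heat-stressed) and black bars give the group mean and SD; levels fall from 77.0% to 11.6% in cooled calves while the 2 groups overlap in every class.

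At single CpGs, 67 of 1753958 sites passed the test of a group difference, 29 higher and 38 lower in heat-stressed calves, on 19 chromosomes. The differences at these 67 sites were large, from 23.5 to 62.2 points with a median of 38.2. The count depended on how the spread was estimated: 1 site passed with the dispersion of each feature alone and 5 with limma. The smallest p belonged to position 27065510 of chromosome 7, which was unmethylated in all 6 cooled libraries (0.00% ± 0.00, n = 6) and stood at 57.7% ± 6.65 in the heat-stressed libraries (n = 5; adjusted p = 1.1e-09, at least 47 reads per library). Position 3960549 of chromosome 28 rose from 44.6% ± 2.0 in cooled to 87.8% ± 3.34 in heat-stressed calves (adjusted p = 5.6e-06), and position 104164347 of chromosome 11 rose from 27.3% ± 10.3 to 89.5% ± 5.44 (adjusted p = 0.00021). These 3 sites also passed with limma (adjusted p of at most 0.021) and with the reads of cooled replicates 3 and 6 summed (at most 0.00016). With the dispersion of each feature alone, only the site of chromosome 7 passed. All 3 were isolated variable CpGs: the nearest tested CpG differed by 2.07 points on chromosome 7, -1.88 on chromosome 28 and 0.15 on chromosome 11. At these 3 sites all heat-stressed libraries lay above all cooled ones, and at 23 of the 67 called sites the groups did not overlap.

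The other sites named as higher in heat-stressed calves were less even within the groups. On chromosome 28, position 7128946 stood at 41.0% ± 30.3 in cooled and 97.4% ± 4.40 in heat-stressed calves. On chromosome 21, position 33025659 stood at 16.2% ± 11.2 and 69.8% ± 18.6, with 10 reads in its shallowest library. On chromosome 22, position 57536806 stood at 44.6% ± 31.5 and 96.9% ± 3.21, and on chromosome 25, position 40540866 stood at 52.4% ± 19.2 and 98.3% ± 1.62. Positions 85950449 and 85960301 of chromosome 12 were at 0.42% ± 0.65 and 0.16% ± 0.39 in cooled and at 49.9% ± 34.7 and 44.1% ± 26.0 in heat-stressed calves. Position 120863089 of chromosome 3 stood at 0.93% ± 1.13 and 44.8% ± 31.8. The adjusted p of these 7 sites was 0.0037 to 0.032. With the reads of cooled replicates 3 and 6 summed, position 33025659 of chromosome 21 (adjusted p = 0.086), position 57536806 of chromosome 22 (0.087) and position 85950449 of chromosome 12 (0.064) no longer passed, with differences of 51.18, 52.05 and 49.41 points against 53.63, 52.29 and 49.49 before, and with limma none of the 7 did (0.067 to 0.97).

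Among sites lower in heat-stressed calves, position 117971209 of chromosome 3 fell most, from 98.4% ± 3.89 to 36.3% ± 37.0 (adjusted p = 0.0077), with 1 heat-stressed library still at 100%. Chromosome 11 held 4 of the 10 named: position 106063613 fell from 87.5% ± 14.7 to 27.6% ± 16.2, position 104178231 from 60.3% ± 35.6 to 0.34% ± 0.76, position 104177822 from 57.3% ± 34.8 to 0.00% ± 0.00 and position 94676888 from 55.6% ± 30.1 to 1.25% ± 1.80. Position 72325196 of chromosome 1 fell from 95.7% ± 2.11 to 38.6% ± 37.2 and position 35979988 of chromosome 28 from 93.7% ± 3.71 to 41.7% ± 24.0. Position 3296811 of chromosome 24 fell from 53.8% ± 30.04 to 0.00% ± 0.00, position 82849674 of chromosome 13 from 51.5% ± 32.8 to 0.29% ± 0.65 and position 39256576 of chromosome 25 from 98.3% ± 1.84 to 48.0% ± 29.2. The adjusted p of these 9 further sites was 0.0058 to 0.041. With the reads of cooled replicates 3 and 6 summed, the 4 sites of chromosome 11 and those of chromosomes 13, 24 and 25 no longer passed (adjusted p of 0.053 to 0.11). Their differences were -59.02 to -44.29 points against -59.95 to -50.37 before. With limma none of the 10 named sites lower in heat-stressed calves passed (0.61 to 0.86). Limma called 5 sites, 3 of them higher in heat-stressed calves, so its other calls were lower sites not named here. The naming rule ranks by difference and left out the lower site of smallest p. This was position 1806542 of chromosome 24, at 93.3% ± 4.38 in cooled and 52.0% ± 7.13 in heat-stressed calves (adjusted p = 1.7e-05 in the quasi-binomial test).

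**Figure D2:**
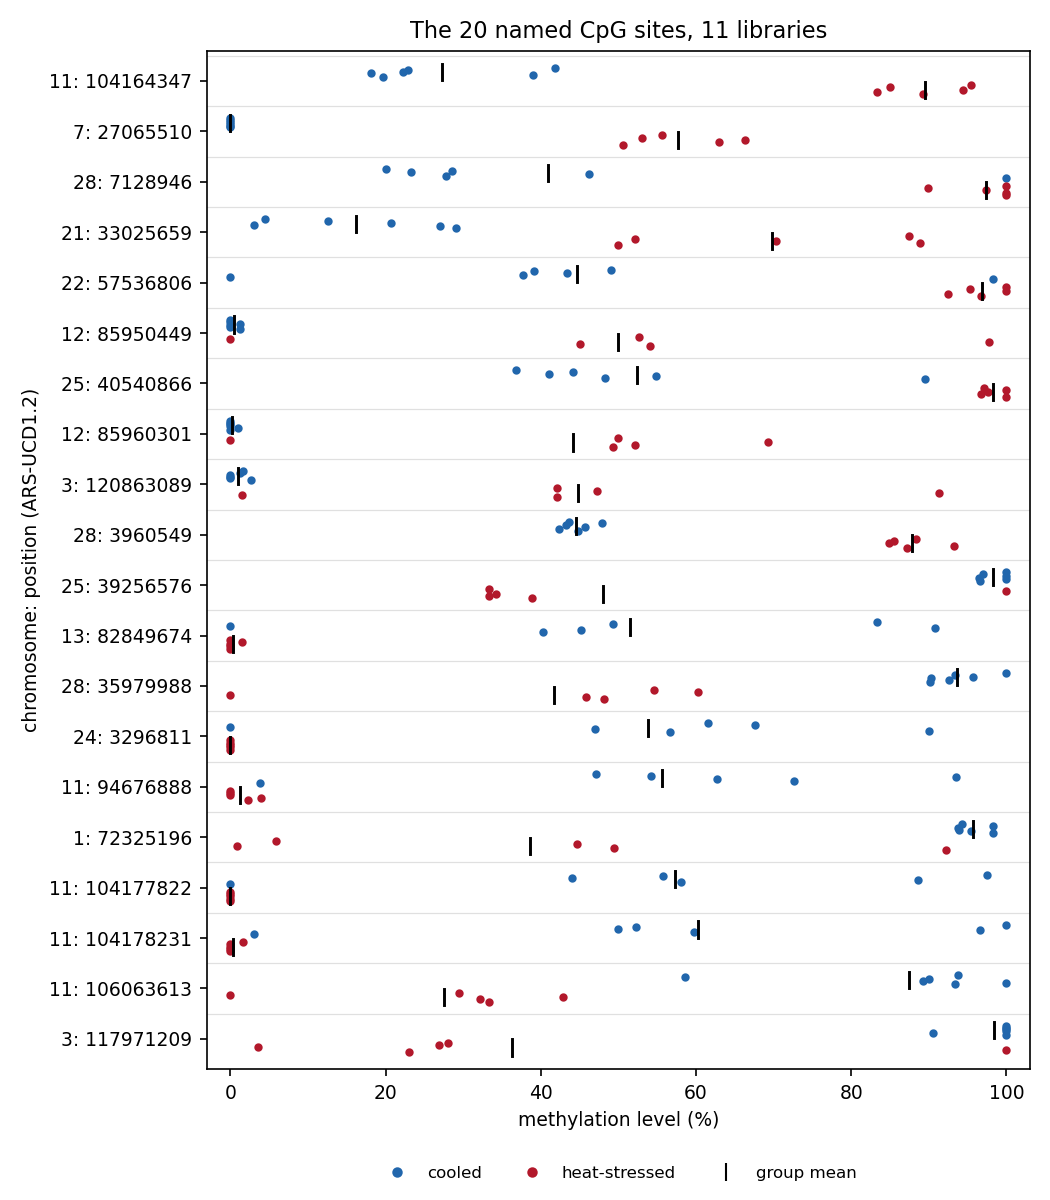
Methylation level (%) of each library at the 20 named CpG sites, in order of the difference and named by chromosome and position. Points are libraries (blue cooled, 6; red heat-stressed, 5) and black bars are group means; at position 27065510 of chromosome 7 the cooled libraries lie at 0.00% and the heat-stressed mean is 57.7%.

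Groups of 3 or more called sites, each within 1 Mb of the next, lay in 5 places. On chromosome 12, 7 called sites spanned positions 85950449 to 86330409. At the 6 of them that were higher in heat-stressed calves, heat-stressed replicate 4 was at 0.00%, the other 4 heat-stressed libraries were at 32.1% or more and no cooled library exceeded 4.0%. On chromosome 25, 4 sites from 40540866 to 40610962 were all higher in heat-stressed calves, and at position 40610934 cooled replicate 1 stood at 98.8% while the other 5 cooled libraries lay between 40.4% and 62.1%. Chromosome 3 held 4 called sites from 117459666 to 118885083, all lower in heat-stressed calves, chromosome 11 held 4 from 104164347 to 104215192 and chromosome 26 held 3 from 51814005 to 51895979.

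The differences at called sites did not extend to the next CpG. Of the 67 sites, 66 had a tested CpG within 50 bp, which moved by a median of 0.90 points in the direction of the site, and at 4 of the 66 the neighbour moved at least 0.5 times as much. Those 4 were 2 pairs of CpGs called together, at positions 40610934 and 40610936 of chromosome 25 and positions 51814005 and 51814007 of chromosome 26. All called sites had a range over the libraries of at least 44.4 points, and 47 of the 66 with a neighbour (71.2%) were isolated variable CpGs, against 48.5% of tested CpGs matched on range and level. The range that defines the class is widened by a group difference too, so leaving the class out removes called sites in part by its definition. With the class left out and p adjusted anew, 7 sites were called, although 20 of the 67 called sites were outside the class. Their unadjusted p stayed the same, so those of the 20 that no longer passed were lost to the adjustment. With the reads of cooled replicates 3 and 6 summed, a pair of libraries that deviated together, 34 sites were called, and with both changes 0. Without cooled replicate 3 the count was 36, without cooled replicate 6 it was 37, without heat-stressed replicate 3 it was 91, and without each other library in turn it was 129 to 287.

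In 1 kb tiles no regional difference passed the test. The quasi-binomial model called 0 of 140601 tiles (smallest adjusted p = 0.973), edgeR and limma also called 0, and 6805 tiles (4.84%) had an unadjusted p under 0.05, of which 4610 were higher and 2195 lower in heat-stressed calves. The tile of smallest p, on chromosome 7 (71561001 to 71562000, 22 tested CpGs), stood at 8.16% ± 2.15 in cooled and 16.5% ± 2.78 in heat-stressed calves (n = 6 and 5, adjusted p = 0.97). A tile on chromosome 14 (78036001 to 78037000) had 8.91% ± 2.92 and 21.6% ± 4.77, and one on chromosome 26 (50722001 to 50723000) had 8.75% ± 1.23 and 15.3% ± 3.20. Tiles on chromosome 4 (119149001 to 119150000) with 81.7% ± 4.63 and 93.2% ± 1.43, on chromosome 13 (43130001 to 43131000) with 86.9% ± 4.28 and 96.1% ± 1.17, on chromosome 1 (72520001 to 72521000) with 62.1% ± 5.32 and 75.7% ± 1.37 and on chromosome 3 (119444001 to 119445000) with 50.6% ± 2.44 and 60.4% ± 2.43 also had higher means in heat-stressed calves. Lower means were found on chromosome 24 (21489001 to 21490000), with 96.6% ± 1.95 and 89.4% ± 1.29, and in 2 further tiles of chromosome 1. The tile from 72325001 to 72326000 had 96.6% ± 1.5 and 77.7% ± 12.6 and the tile from 61957001 to 61958000 had 95.7% ± 1.55 and 82.4% ± 7.46. Without isolated variable CpGs the differences of these 2 tiles were 0.10 and 0.16 points, and those of 3 others shrank, from 13.57 to 3.08 in the tile of chromosome 1 from 72520001, from 11.51 to 7.37 in that of chromosome 4 and from -7.22 to -4.68 in that of chromosome 24, while the other 5 changed by at most 0.09. Isolated called sites lay in 3 of these tiles, at positions 72325196 and 61957034 of chromosome 1 and 119149922 of chromosome 4. All 10 had an adjusted p of 0.97.

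**Figure D3:**
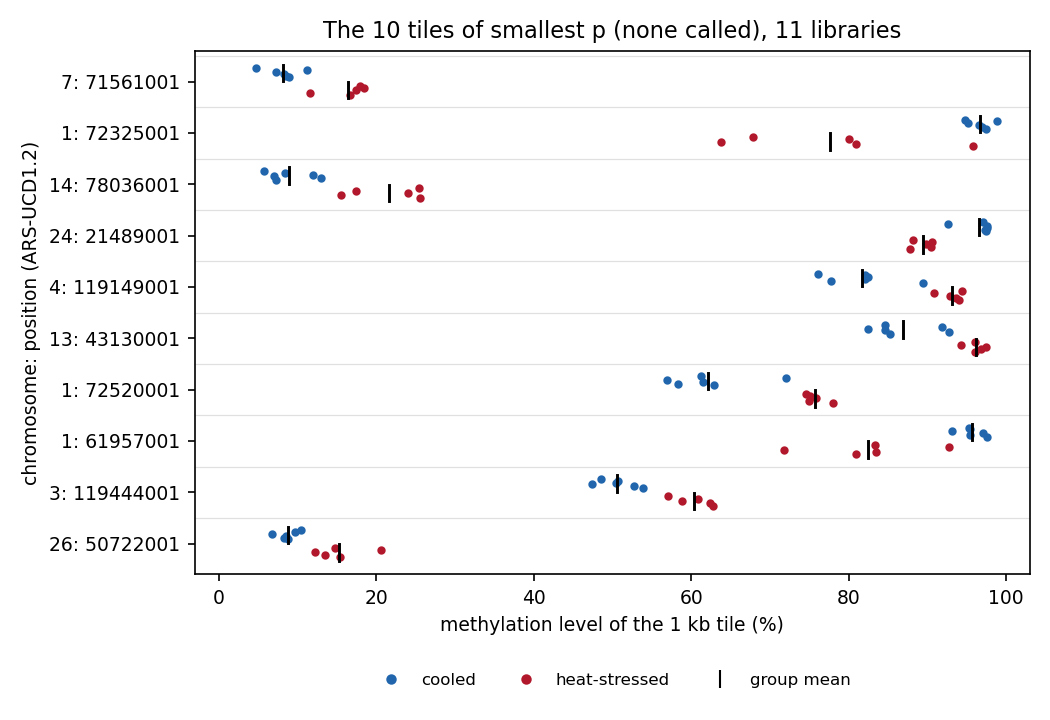
Methylation level (%) of each library in the 10 tiles of 1 kb with the smallest p, in order of p from the top and named by chromosome and start. Points are libraries (blue cooled, 6; red heat-stressed, 5) and black bars are group means; no tile passed the adjusted threshold, and the groups differ by 8.29 points in the tile of chromosome 7, which has the smallest p.

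With no spread between animals in the error, 26679 sites (16011 higher in heat-stressed calves) and 22609 tiles (15292 higher) had an adjusted p under 0.05. The median dispersion was 1.29 times binomial at sites and 2.50 times at tiles. The median SD between the 11 libraries was 0.707 points in tiles under 20%, 5.30 in tiles at 20 to 80% and 2.40 in tiles at 80% or more.

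The libraries themselves were not equally distinct. Over 23311 isolated variable CpGs the deviations of cooled replicates 3 and 6 correlated with r = 0.795 across CpGs, which are not independent replicates, while the other 54 pairs of libraries lay between -0.230 and 0.144. At 17 CpGs 1 or both of these replicates were at 10% or lower while the other 9 libraries were at 85% or higher. At 17 of the 17 both were (100%, exact Clopper-Pearson 95% interval 80.5 to 100%, which counts the CpGs as independent). In no other pair did that share exceed 20%. Sharing was weaker at intermediate levels: of 440 CpGs at 35 to 65% in 1 or both, with the other 9 libraries at 85% or higher, both were at 35 to 65% at 185 (42.0%, at most 12.1% in another pair) and 1 was at 85% or higher at 158. With at least 30 reads in both, the share was 76.3% of 194 CpGs, among isolated variable CpGs 71.4% of 210, and with both limits 85.6% of 139. At CpGs of mean level 20 to 80%, with isolated variable CpGs left out, the counts of cooled replicates 3 and 6 still differed by more than sampling noise. The chi-square was 1.54 per degree of freedom, against 1.91 to 3.06 in the other pairs, which sets them apart as libraries and not as calves. The labels list them as separate samples and the tests count both; were they 1 calf, the cooled group would hold 5 animals and not 6, and p-values that count 6 would be too small. Cooled replicate 4 had 4734 tiles outside the range of the others and at least 15 points from their mean, against 851 to 1180 in each other library.

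**Figure D4:**
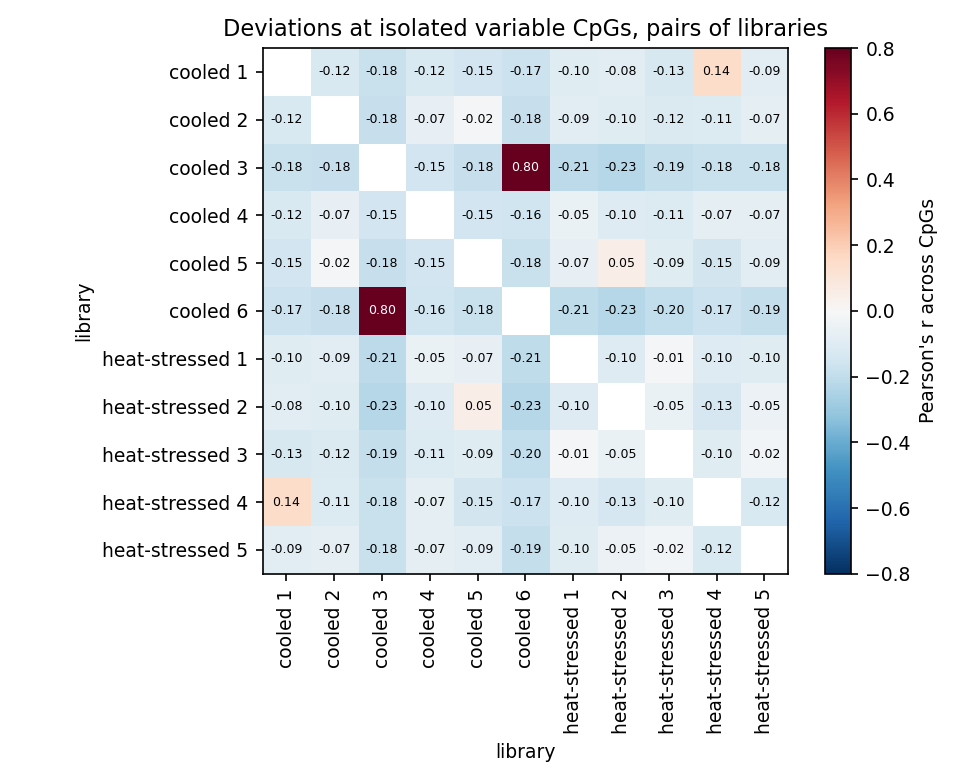
Pearson's r across isolated variable CpGs between the deviations of each pair of libraries from the mean of the 11, on a colour scale from -0.8 to 0.8. Cooled replicates 3 and 6 stand at 0.795, and the highest other pair, cooled replicate 1 with heat-stressed replicate 4, at 0.144.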

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

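Every test in this part except that of a second calf's DNA was chosen after the result was seen. Far samples were looked for in 146 groups of values, and 23 held a sample whose gap to its nearest neighbour was too large a share of the range; chance gives about 1 in 20 groups, and the classes and chromosomes share CpGs.

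Cooled replicate 4 lay far below the other cooled libraries in mean level at CpGs of 80% or more (90.8%), in tiles with 1 to 4 tested CpGs (75.8%) and with 5 to 14 (68.7%), and on chromosomes 5 (53.5%), 6 (52.8%), 8 (47.0%), 20 (54.9%) and 26 (53.1%), and far above them in outlying tiles (4734). Tiles that stood at 20 to 40% in the other libraries were on average 2.27 points higher in it, while tiles at 80 to 90% deviated by -2.79 points. A difference in bisulfite conversion would move tiles one way, but 35.5% of its outlying tiles were higher (1680 tiles, against at most 543 in any other library), and its 136003357 read calls exceed the median of 127210800. Variants private to that calf would leave neighbouring CpGs in place. At 38.5% of its 3022 outlying CpGs the neighbour moved at least 0.5 times as much, against a median of 11.9% in the others. Cooled replicate 3 reached 40.1% of 314 CpGs and cooled replicate 6 28.55% of 613. An outlying CpG lay beyond all other libraries, so CpGs at which that pair deviated together are missing from both shares. The share is thus above the median but within the range of the others. By number, the neighbour moved that much at 1164 outlying CpGs of cooled replicate 4, against at most 209 in any other library. This argues against private variants at single CpGs for those 1164 CpGs, while its other outlying CpGs may be such variants. DNA of a second calf would pull its private isolated CpGs off the levels of a single genome. Of these, 82.2% lay at 10% or lower or at 35 to 65%, against 49.0 to 82.3% in the other libraries (49.0% of only 49 CpGs in cooled replicate 3). They were chosen for lying more than 25 points beyond the other libraries. Diluted variants can miss that choice or fall at 35 to 65%, so the test cannot exclude a second calf's DNA. A different cell makeup of that biopsy may account for the 4734 tiles and stays open, since no methylation profile of other liver cell types was used; no biological explanation from the study design was tested, as both treatments hold other calves without this pattern.

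At named sites single libraries stood apart within their group, given here as values. On chromosome 3 at position 117971209, cooled replicate 2 was at 90.5% and heat-stressed replicate 2 at 100%. On chromosome 11, heat-stressed replicate 5 was at 1.69% at position 104178231 and cooled replicate 5 at 58.6% at position 106063613. On chromosome 12 at position 85960301, cooled replicate 2 was at 0.96% and heat-stressed replicate 4 at 0%. Heat-stressed replicate 4 was also at 1.45% at position 82849674 of chromosome 13, at 100% at position 39256576 of chromosome 25 and at 89.8% at position 7128946 of chromosome 28, where cooled replicate 1 was at 100%. Cooled replicate 1 was at 89.5% at position 40540866 of chromosome 25, and heat-stressed replicate 3 at 0% at position 35979988 of chromosome 28. In the tile from 71561001 of chromosome 7 heat-stressed replicate 2 was at 11.6%, and in the tile from 21489001 of chromosome 24 cooled replicate 5 was at 92.7%.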

How the results depend on the processing

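Alternatives with isolated variable CpGs left out, with cooled replicates 3 and 6 combined or with cooled replicate 4 left out beside them were chosen after the results were seen. The mean difference kept its sign and missed the threshold under all alternatives run (0.121 to 0.397 points with each library left out, 0.275 to 0.525 otherwise, the highest with methylated reads over all reads). Tiles stayed at 0 calls except with binomial error only (22609) and without single libraries (0 to 2: 1 without cooled replicate 1, cooled replicate 5 or heat-stressed replicate 4, and 2 without heat-stressed replicate 1). The 67 called sites became 1 with the dispersion of each feature alone, 5 with limma (3 higher in heat-stressed calves) and 6 with limma after median-centring (3 higher), 125 with edgeR (63 higher), 26679 with binomial error only, 111 at an adjusted p under 0.10 and 115 with strands apart. They became 7 without isolated variable CpGs, 34 with cooled replicates 3 and 6 summed, 0 with both changes, and 124 with the sum and without cooled replicate 4. Leaving out 1 library gave 36 to 287 sites: 287, 144, 36, 233, 195 and 37 without cooled replicates 1 to 6, and 129, 129, 223 and 132 without heat-stressed replicates 1, 2, 4 and 5; without heat-stressed replicate 3 the 91 stayed within 1.5 times. Of the 20 named sites 20 were called by edgeR, 3 by limma, 10 with the summed replicates and 1 with the dispersion of each feature alone. The site at position 27065510 of chromosome 7 was called under each of the 26 alternatives that tested it. The alternative without isolated variable CpGs did not test it, because the site belongs to that class. The difference changed sign in tiles with 60 or more tested CpGs (-0.001 with no upper limit on coverage, -0.072 to 0.074 with each library left out), in CpGs under 20% (-0.105 to 0.013 with each left out, 0.013 without cooled replicate 5), and, without isolated variable CpGs, in the tiles of chromosome 1 from 72325001 (0.10) and 61957001 (0.16), which lose the CpG that carried the difference; for the others the cause was not tested. No paired analysis was possible because the labels give no replicate numbers and the numbers used here pair nothing. Promoters, gene bodies and gene lists were not run. What depth limits was not separated from other causes: with at least 20 reads 49 sites were called, and in simulated data of this depth a change of 20 points was called in 12% of sites and 62.0% of tiles.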

Other observations

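Tests of whether other groupings give as many sites or tiles, of neighbouring CpGs, of the shared genome, of siblings and of a shared batch, and the sums of cooled replicates 3 and 6 and of other cooled pairs, were chosen after the results were seen; the splits with isolated variable CpGs left out, for binomial error only, for tiles at an unadjusted p, for wide gaps and the chi-square test were set before their results.

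The level of the X chromosome followed the number of tested CpGs in the tile differently from that of the autosomes. In tiles with 60 or more tested CpGs the mean level was 21.2% ± 0.442 on X and 11.6% ± 0.193 on the autosomes (SD over 11 libraries), and X was higher in each of the 11 libraries, with 20.6 to 21.8% on X and 11.2 to 11.9% on the autosomes. In tiles with 15 to 29 tested CpGs the order was the opposite, 26.4% ± 0.253 on X and 51.1% ± 0.404 on the autosomes. X was also lower with 5 to 14 (61.1% and 70.0%) and with 30 to 59 (13.4% and 28.4%). In tiles with 1 to 4 the levels were 77.9% ± 0.660 and 77.1% ± 0.598. All 11 libraries measured the same CpGs, so their agreement does not replicate a difference between X and the autosomes. The class with 1 to 4 tested CpGs held 3453 CpGs of X and that with 60 or more held 1174. The share of reads on X was 1.09 to 1.18% in the 11 libraries.

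The 67 called sites may be mostly sequence variants at single CpGs, since a C-to-T variant is read as an unmethylated cytosine: the median ratio of the neighbour's difference to that of the site was 0.020. A regional methylation difference at most of them is argued against by the upper exact 95% limit of 14.8% for the share of sites whose neighbour moved at least 0.5 times as much. That limit counts the sites as independent, although the sites with such a neighbour were pairs called together. Counting cooled replicates 3 and 6 as 2 animals is a further candidate explanation of how many sites pass, not of their differences: the count was 34 with their reads summed and 68 to 122 with those of any other cooled pair, and at the 33 sites no longer called the median difference went from 39.84 to 37.62 points and the median cooled SD from 11.97 to 13.17, with 16 of them still at or under the largest p called before (1.9e-06, against 8.7e-07 with the sum). Chance cannot be excluded: 40 of 100 splits of the 11 libraries (the real one included) gave 67 sites or more. The highest other split gave 359. The real split keeps cooled replicates 3 and 6 together. The 42 other splits that do so had a median of 137.5 sites, and the 57 that parted them a median of 5.0 (at most 51). All splits with as many sites as the real one therefore kept the pair together, and among such splits the real 67 lay under the median. This points to a structure of the libraries. Whether heat stress contributes at single sites stays open.

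Chance could not be excluded for the other counts above 0 either. With isolated variable CpGs left out and p adjusted anew, 43 of 100 splits gave the real 7 sites or more, with 100 in the highest other split. For sites called with binomial error only, 41 of 100 splits gave the real 26679 or more, with 32640 in the highest other. For tiles at an unadjusted p under 0.05, 52 of 100 splits gave the real 6805 or more, with 9670 in the highest other. The real count of called tiles is 0, which all 100 of 100 splits must reach, so the splits decide nothing there; the highest other split called 7. At 3 CpGs, positions 27065510 of chromosome 7, 104164347 of chromosome 11 and 3960549 of chromosome 28, the nearest libraries of the groups lay 30 points or more apart, and 203 of all 462 splits gave 3 or more such CpGs, with 44 in the highest other; all 203 were among the 210 splits that kept cooled replicates 3 and 6 together.

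Cooled replicates 3 and 6 may hold the same genome, as 2 samples of 1 calf or of identical twins would. Both were at 10% or lower at 100% of the 17 CpGs at which 1 was, with the other 9 libraries at 85% or higher. The lower exact 95% limit of 80.5% lies above the about 1 in 7 that full siblings would share where both parents carry the variant. That limit counts the 17 CpGs as independent, which was not tested. It may be too high, and it argues against full siblings only under that assumption. At 35 to 65% only 42.0% of 440 CpGs were shared, less than 1 genome would give without counting noise. With at least 30 reads in both, 76.3% of 194 CpGs were shared, and 85.6% of 139 isolated variable CpGs of that depth. At 35.9% of the 440 CpGs 1 of the 2 was at 85% or higher, where full siblings with 1 carrier parent would have about 2 in 3. That share was 5.2% of the 194 and 0.7% of the 139. Sharing was thus higher at deeper CpGs, and what else lowers it at shallow CpGs was not determined. A single library deposited under both names is argued against by the chi-square of 1.54 per degree of freedom between their counts. A shared batch or cell makeup stays open beside a shared genome: at 156487 CpGs of intermediate level with a range under 30 points their correlation (-0.058) exceeded that of the median pair by 0.042, with -0.056 in the highest pair, but that limit removes CpGs such a cause would move, and the second principal component of variable tiles (14.4% of variance) held both together at 0.64 and 0.62.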
